A study of Danio rerio with 2 samples.

How the data were processed

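RNA-seq was deposited for 2 zebrafish libraries, 1 labelled wild type and 1 labelled salvianolate-treated, both labelled as total RNA of cardiac tissue. Salvianolate is a preparation of salvianolic acids from the root of Salvia miltiorrhiza. The groups were taken from the labels, where the treatment stands in the genotype field. The labels give no age, dose, duration or number of animals, and 1 title speaks of embryos. Per the file headers, the count columns of the single-library files are named AB72h for the wild-type library and DSDF for the treated library; what these names stand for is not given in the sources used here.

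The deposited table of the series holds estimated counts and FPKM for 26597 genes in both libraries, per the file headers. The authors' estimated counts (expected counts) are not normalised, and 10.3% of the values of the wild-type library and 10.4% of those of the treated library are not whole numbers. The deposited FPKM values are scaled to gene length and library size and were used only as an alternative. The deposited single-library files held the same count for all 26597 genes as the table of the series. Per the submitters' processing notes, the tools were fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, DESeq2 and edgeR, and the genome build was danRer11. The role of each tool, its settings and the annotation are not given in the sources used here. The table has 25197 Ensembl gene IDs and 1400 assembled loci that carry no gene ID. Symbols came from a table of IDs and names, which gave a name to 23499 of the Ensembl IDs. That table writes many genes in capitals, and 1634 symbols belong to more than 1 gene ID. No annotation of the authors' build was used, so no coordinates are given. Reads shared between near-identical copies, such as globin, opsin, trypsin and hatching enzyme genes, may be split between copies by the authors' estimation, so values of single copies are uncertain.

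The estimated counts were rounded to whole numbers. Library sizes were scaled by the TMM factors of edgeR 4.0.16 in R 4.3.3. The log2 ratio of treated over wild type was computed from counts scaled to library size (CPM) after adding 0.5 counts to each gene and library. A gene entered with at least 1 CPM in 1 or both libraries. It was counted as different at a scaled fold of at least 2 when the exact 95% counting interval of the ratio (Clopper-Pearson, from the share of both libraries' counts) excluded 1. With 1 library per group there is no replicate check, no test between conditions and no p-value. Intervals, and the CPM that 3 counts amount to in a library, cover counting error only. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

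Before the data were examined, 38 gene lists were written, covering lysosome, heart, metabolism, stress, blood, proliferation and other tissues. A list is given by the median log2 ratio of its members above the floor, the exact binomial order-statistic 95% interval of that median, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile under 2.5 is called below, and one over 97.5 above, the random lists; it describes these 2 libraries only. Lists with under 5 members above the floor have no percentile. Of 1666 list names, 604 were in the names table exactly as written and 1062 were dropped, as the design had set. Because most of the dropped names differ only in capitals or in a copy suffix, an alternative chosen after seeing the data also matched names in capitals and without the suffix, with all genes of that name entering, and it placed 1552 names. This wider matching was first used as the main one and was made the alternative after its list values had been seen, because the design asks for exact names; both are given wherever they differ in a call. Another 9 lists were written after the data were examined and use the wider matching.

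Genes were named by a rule fixed before the data were examined. It takes the 12 highest and the 12 lowest ratios among counted genes with at least 10 CPM in the higher library and a symbol that is not a clone name; the highest, lowest and most abundant member of each list; a fixed set of heart, lysosome and stress genes; and the 5 most abundant genes of each library. Clone names were read as a clone prefix followed by digits, so that gene names in capitals that begin with the same letters stayed in. The fixed set was looked up by the wider matching. Some genes of the fixed set and 1 of the lists are not reported here.

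The alternatives were total count, DESeq2 1.42.0 median-of-ratios and upper-quartile scaling; no floor and a floor of 5 CPM; a prior of 2 counts; FPKM with a pseudocount of 0.5; folds of 1.5 and 4; no counting interval, and an interval that excludes the fold of 2; genes with a symbol only; 40 bins; and lists without their most abundant member. An alternative without the eye and exocrine pancreas lists was added after seeing the data. The steps were tested on counts simulated for these libraries over 26597 genes, of which 200 were altered. The rule called 99.0% of genes altered 3-fold and 99.0% of those altered 6-fold, and 48 of 19486 unaltered genes above the floor. The interval held the true ratio for 95.7% of genes. Of 200 simulated lists of 30 genes without a shift, 6.5% fell outside the percentile limits, and with a shift of 0.3 on the log2 scale 100.0% lay above the upper limit. The simulated libraries held counting error only, and the simulated lists were of randomly drawn genes. These rates therefore do not cover differences between animals or libraries, or lists whose members vary together.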

Results

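RNA of 1 wild-type and 1 salvianolate-treated zebrafish library, both labelled as cardiac tissue, was sequenced, and the estimated count of each gene was deposited. The wild-type library held 19531808 estimated counts and the salvianolate-treated library 19295536, a ratio of 0.988. Counts were present for 23725 genes in the wild-type and 23822 in the treated library, and 19187 and 19526 genes reached 1 CPM. A count of 3 corresponds to 0.157 CPM in the wild-type and 0.152 CPM in the treated library. The most abundant genes were eef1a1l1, a translation elongation factor, with 16080 CPM in wild type and 13705 CPM in treated, and actc1b, a muscle actin, with 14389 and 14860 CPM. The 10 most abundant genes took 7.6% and 7.3% of the counts.

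The comparison asks how the transcriptome of the treated library differs from that of the wild-type library; the series describes an interest in how salvianolate acts against cardiotoxicity. In the treated library, 9 of 22 eye genes and 11 of 13 exocrine pancreas genes were at least 2-fold higher, and none of either list was 2-fold lower. Most genes of the skeletal muscle and neuron lists had ratios above 1, but only 2 of 23 and 2 of 16 reached a fold of 2. Ratios of erythroid genes, globins among them, and of most cell cycle genes were below 1, with 2 of 17 and 0 of 17 at least 2-fold lower. The lists of pigment cells and of skin lay below random lists, and that of cartilage, bone and notochord above, each with members on both sides of 0. The exocrine pancreas list had a median log2 ratio of 1.52 (interval 1.16 to 1.78, 13 members) and the erythroid list -0.66 (-0.86 to -0.51, 17 members). Of 19829 genes above the floor, 532 were at least 2-fold higher and 143 at least 2-fold lower in the treated library, and 19154 met neither rule. With FPKM in place of counts the numbers were 334 and 81. Across genes the libraries correlated with Pearson's r of 0.987 and Spearman's rho of 0.986 on log2(CPM + 1), where genes are not independent replicates. The split, 78.8% higher, runs opposite to the series' own design text, which gives 109 genes up-regulated and 565 down-regulated in the treated group. With the ratio turned, the counts would be 143 higher and 532 lower. The settings behind the series' numbers are not given in the sources used here, and counts by the present rule vary with the fold. They were 1204 and 523 at 1.5-fold and 75 and 21 at 4-fold, so a similar size is not evidence of an exchange. Whether the labels or the text's direction are exchanged is not known, and every direction below follows the library labels. Each group is 1 library, so no difference here has a replicate check.

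**Figure D1:**
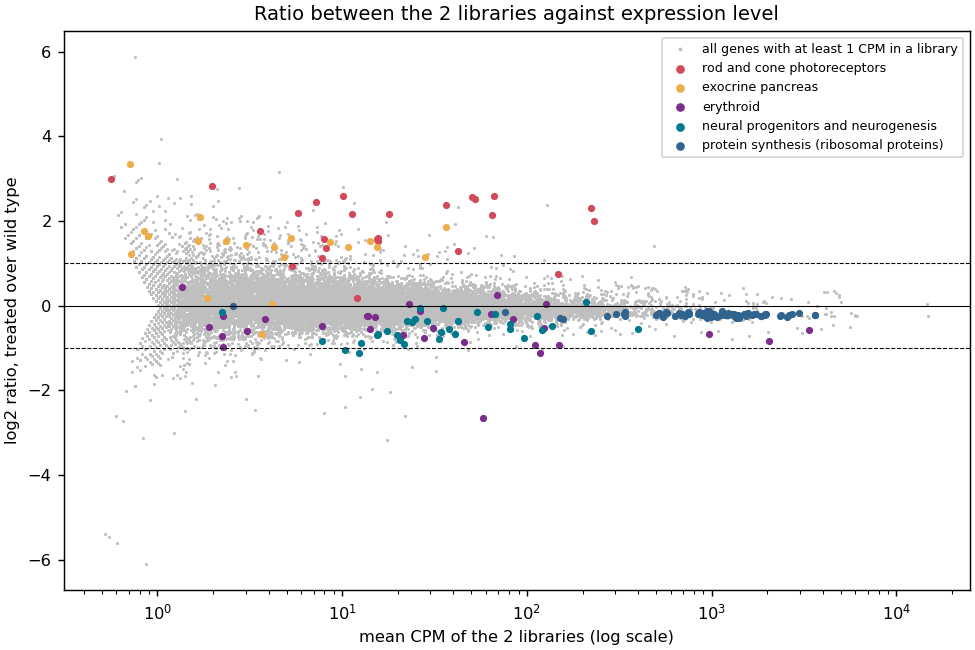
Log2 ratio of treated over wild type (vertical axis) against the mean CPM of both libraries (horizontal axis, log scale) for 19829 genes, 1 point per gene, with members of 5 lists coloured (names also matched in capitals) and dashed lines at a fold of 2. Photoreceptor genes (median 2.16) and 19 of 20 exocrine pancreas genes lie above 0, and erythroid, neural progenitor and ribosomal protein genes lie mostly below 0. The photoreceptor and neural progenitor lists were written after the data were examined, so their place is not independent evidence.

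Among the 12 highest ratios of named genes with at least 10 CPM were those of opsin, transducin and outer segment genes. The cone opsin genes opn1lw2 (ENSDARG00000044861), opn1mw1 (ENSDARG00000097008) and opn1sw2 (ENSDARG00000017274) stood at 74.1, 18.8 and 14.5 CPM in wild type and at 368, 114 and 86.4 CPM in the treated library. They were higher by 4.96-fold (4.69 to 5.26), 6.06-fold (5.43 to 6.80) and 5.95-fold (5.25 to 6.79). OPN1SW (ENSDARG00000045677), a short-wavelength opsin, went with them at 41.6 and 216 CPM, a log2 ratio of 2.37 (2.26 to 2.48). The transducin subunit genes GNAT2, GNGT2 and gnb3b had ratios of 2.37, 2.52 and 2.33, and the cone opsin kinase gene GRK7 2.42. PRPH2 and rom1a, which encode proteins of the outer segment disc rim, had 2.59 and 2.46, and PDC, which encodes the transducin-binding phosducin, had 2.80. GUK1, a guanylate kinase gene, completed the 12 highest at 2.27. In the eye list, 22 of 22 members had a ratio above 0 and 9 were at least 2-fold higher, with a median of 0.66 (0.31 to 1.58, percentile 100). Lens crystallin genes of that list differed less: the most abundant, crybb1l2, stood at 1006 and 1246 CPM, a ratio of 0.31 (0.28 to 0.34).

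Genes of the exocrine pancreas, most of them digestive enzyme genes, were higher as a group. Of 13 members, 11 were at least 2-fold higher and none was lower by that rule (percentile 100). Levels were low, with a median of 1.73 CPM in wild type and 3.50 CPM in treated. Some members, such as ela2 at 0.837 and 2.485 CPM, passed the floor only through the treated library. The list kept its call with a floor of 5 CPM in 1 or both libraries, which is a weak check. Members such as prss59.1, at 2.35 and 6.19 CPM, again pass that floor only through the treated library. It also leaves out ela2l and amy2al1, the 2 members not counted as higher. The trypsin gene prss59.2 (ENSDARG00000073742) stood at 15.6 and 57.3 CPM, a log2 ratio of 1.87 (1.69 to 2.06), and the chymotrypsin-like gene ctrl at 0.628 and 2.79 CPM, a ratio of 2.11 (1.23 to 3.19). The amylase gene amy2al1 stood at 4.08 and 4.21 CPM. The intestine list had a median of 0.31 (-0.30 to 0.56, 14 members, percentile 99.7), with the tight junction gene cldn15lb at 0.99 and the apolipoprotein gene apoa4b.2 at -0.57. With a floor of 5 CPM the intestine median was -0.028 at percentile 45.0. Under exact names its place above the random lists thus rests on members at low levels. Of the 14 members, 4 had an interval above a ratio of 1 and 3 below. The wider matching gave 0.347 (0.034 to 0.558, 30 members, percentile 100). Liver and plasma protein genes went both ways. Their median was -0.17 (-0.26 to -0.005, 31 members, percentile 0.635), 20 members had an interval below a ratio of 1, and 5 were at least 2-fold higher. The most abundant, apoa1b, had a ratio of -0.22, the vitellogenin gene vtg7 -0.91 and the sex hormone-binding globulin gene shbg, at 0.262 and 1.57 CPM, 2.47 (1.21 to 4.31).

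Skeletal muscle genes had a median of 0.20 (0.08 to 0.30) with 19 of 23 members above 0 (percentile 100). The myosin heavy chain gene myhb had a log2 ratio of 1.47 (1.31 to 1.64), and actc1b had 0.05 (0.04 to 0.05). Genes of neurons and glia had a median of 0.25 (0.07 to 0.45, 16 members, percentile 100), with 13 members above 0 and 3 below. The highest ratio was that of the myelin basic protein gene mbpa at 2.93 and 8.82 CPM, 1.58 (1.15 to 2.05). The most abundant member, the tubulin gene tubb2b, had the lowest ratio, -0.187 (-0.210 to -0.165), from 1732 and 1521 CPM. The list of cartilage, bone and notochord had 0.32 (-0.17 to 0.69, 13 members, percentile 99.99), with the aggrecan gene acanb at 0.90 and the notochord transcription factor gene tbxta at -0.41.

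Heart genes were at low levels in both libraries. MYL7 (ENSDARG00000019096), the myosin light chain gene of heart muscle, stood at 19.2 CPM in wild type and 14.7 CPM in treated, a log2 ratio of -0.38 (-0.61 to -0.16). The atrial myosin gene myh6 had a ratio of -0.19 (-0.66 to 0.28), cmlc1 -0.17 (-0.46 to 0.12), and the more abundant of the genes named TNNT2, cardiac troponin T, stood at 7.22 and 4.97 CPM. The natriuretic peptide gene nppa had 16.8 and 9.03 CPM, a ratio of -0.89 (-1.17 to -0.63), and nppb 0.994 and 1.07 CPM, not a detectable difference at this depth. The cardiac sarcomere list, which also holds genes of other muscle, had a median of 0.05 (-0.17 to 0.20, 16 members, percentile 80.5); with the wider matching it had 0.098 over 40 members, at percentile 99.7. Genes of calcium and ion handling had 0.32 (-0.01 to 0.47, 10 members, percentile 99.8), with calm1a at 0.30 and the calcium pump gene atp2a2a at -0.25. This list is not confined to heart genes either, since calm1a stood at 170 and 208 CPM, well above MYL7. Its place does not show a rise in heart, and the skeletal muscle and neuron lists also lay above the random lists. Cardiac transcription factors (-0.07, 6 members, percentile 25.1) and cardiac stress and fetal genes (0.005, 9 members, percentile 56.2) lay within the random lists. Epicardium and fibroblast genes had 0.28 (-0.33 to 1.36, 8 members, percentile 99.4), with 5 members above 0 and 3 below. The smooth muscle actin gene acta2, the highest, stood at 28.9 and 74.5 CPM. The most abundant member, the collagen gene col1a1a, stood at 4415 and 3879 CPM, a ratio of -0.19 (-0.20 to -0.17). With a floor of 5 CPM the median of the list was 0.105 and with the wider matching 0.018, both within the random lists. Endothelium and endocardium genes had -0.13 (-0.24 to 0.04, 15 members, percentile 4.09), and -0.135 over 28 members, at percentile 0.46, with the wider matching.

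**Figure D2:**
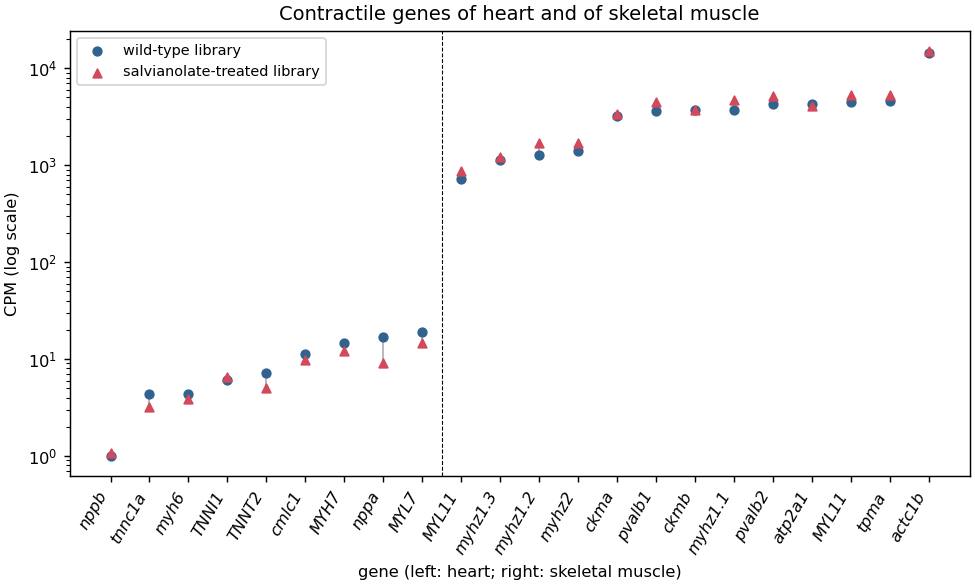
CPM (vertical axis, log scale) of contractile and natriuretic genes of heart (left of the dashed line) and contractile genes of skeletal muscle (right) in the wild-type library (circles) and the treated library (triangles), 1 library each, from lists written after the data were examined; a name shown more than once stands for several gene IDs. MYL7, the highest of the heart genes, is at 19.2 and 14.7 CPM, and actc1b at 14389 and 14860 CPM.

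Erythroid genes were lower in the treated library, with 0 of 17 members above a log2 ratio of 0 and 13 with an interval below a ratio of 1 (percentile 0). The embryonic globin gene hbbe3 (ENSDARG00000038147) stood at 99.4 and 15.9 CPM, a ratio of -2.64 (-2.82 to -2.47), the lowest among the named genes. The globin genes hbae1.1 and hbae3 had -1.13 and -0.58, the latter from 4029 and 2703 CPM. Cell cycle genes had a median of -0.31 (-0.34 to -0.27, 17 members, percentile 0), 16 members had an interval below a ratio of 1, and none was 2-fold lower. The kinetochore gene ndc80 had the lowest ratio, -0.49 (-0.62 to -0.35), and the cyclin gene ccnb3 the highest, 0.007 (-0.20 to 0.21). Ribosomal protein genes had -0.20 (-0.24 to -0.16), with 9 of 9 intervals below a ratio of 1 and rpl7a at 2904 and 2522 CPM; the percentile was 2.75, and 0 over the 75 members of the wider matching. Pigment cell genes had -0.26 (-0.53 to 0.14, 7 members, percentile 0.16), led by the pteridine synthesis gene gch2 at -0.53. Skin and epithelium genes had -0.17 (-0.27 to -0.007, 31 members, percentile 0.19), where krt4 and cyt1l, keratin genes, had -0.50 and -0.63 and krt92 had 0.71.

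Other genes among the 12 lowest were of several kinds. The hatching enzyme genes he1.1 (ENSDARG00000023656) and he1.2 stood at 37.5 and 13.7 CPM in wild type and at 6.19 and 2.33 CPM in the treated library, log2 ratios of -2.59 (-2.89 to -2.32) and -2.54 (-3.04 to -2.09). RHCG, an ammonium transporter gene, stood at 17.5 and 3.30 CPM, ponzr3 and ponzr4 had log2 ratios of -2.16 and -1.65, and the glucose-6-phosphatase gene g6pc1a.1 had -1.38. The Notch target gene her4.3 had -1.12, gvin1l2 -1.21 and the protease gene tmprss9 -1.09.

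Lysosomal genes, which the series' design text names as a pathway found in these libraries and whose lists are therefore not independent evidence, did not stand apart from random lists under exact names. Lysosomal hydrolases had a median of 0.03 (-0.34 to 0.25, 9 members, percentile 63.4) with 1 member at least 2-fold lower, the cathepsin gene ctslb at 3.92 and 1.32 CPM. The most abundant member, the cathepsin gene ctsla, stood at 784 and 803 CPM. The wider matching gave 56 hydrolase genes and a median of -0.111 (-0.24 to -0.02), at percentile 0.23, so the place of this list depends on the matching. Among genes that enter only with it, CTSD and CTSB had log2 ratios of -0.25 (-0.30 to -0.20) and -0.24 (-0.32 to -0.16), and the acid phosphatase gene ACP5, at 23.1 and 7.76 CPM, had -1.57. Lysosomal membrane and accessory proteins had -0.02 (9 members, percentile 48.5), and -0.075 over 36 members of the wider matching, at percentile 7.99, with lamp1b at -0.15 (-0.34 to 0.04); LAMP2 had -0.15 (-0.27 to -0.02). Vacuolar ATPase genes had -0.13 over 5 members (percentile 13.0) and 0.108 (-0.07 to 0.22) over 24 members of the wider matching, at percentile 99.9. Autophagy genes (-0.004, 8 members, percentile 46.2) and plasma membrane solute carriers (0.07, 8 members, percentile 79.1) lay within the random lists.

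Stress, immune and metabolic lists lay within the random lists under exact names. The medians were 0.015 for oxidative stress (17 members, percentile 69.4), 0.08 for heat shock (11, percentile 79.6), -0.08 for the unfolded protein response (12, percentile 27.14), 0.06 for inflammation (18, percentile 68.3) and -0.07 for leukocytes (16, percentile 15.8). Xenobiotic metabolism had 0.04 (27, percentile 77.8), glucocorticoid response -0.08 (10, percentile 21.4) and the circadian clock 0.15 (16, percentile 95.02). Nuclear oxidative phosphorylation had 0.029 (25, percentile 96.7), fatty acid oxidation 0.05 (7, percentile 82.3) and glycolysis and hypoxia -0.21 (6, percentile 3.83). With the wider matching, oxidative stress, the circadian clock, nuclear oxidative phosphorylation, fatty acid oxidation and glycolysis lay above the random lists. Their medians were 0.063, 0.175, 0.027, 0.040 and 0.042. The interval of the median lay above 0 only for nuclear oxidative phosphorylation (0.008 to 0.048). It included 0 for oxidative stress (-0.104 to 0.105), the circadian clock (-0.099 to 0.277), fatty acid oxidation (-0.063 to 0.096) and glycolysis (-0.131 to 0.174). Of 38 lists, 16 lay above and 8 below the random lists under that matching. Single genes went further than their lists: HMOX1, the haem-degrading enzyme gene, had a log2 ratio of -0.83 (-1.07 to -0.60), casp8 had -1.09 (-1.66 to -0.55), gstp1.1 1.18 (0.76 to 1.62), the fatty acid-binding protein gene fabp10a, at 1.78 and 5.78 CPM, 1.69, and apoeb -0.72 (-0.74 to -0.69). SOD1 and SOD2 had 0.18 and 0.19, and CAT 0.06. MMP9 had 0.11 (-0.28 to 0.51), and il1b was under the floor at 0.471 and 0.304 CPM. Too few members were matched exactly for a percentile of mitochondrially encoded genes (-0.09, 2 members) and of cholesterol genes (0.14, 4 members), and no oocyte gene was above the floor; the wider matching put mitochondrially encoded genes (0.116, 13 members, percentile 99.76) and cholesterol genes (0.148, 27 members, percentile 98.56) above the random lists and oocyte genes (-0.117, 7 members, percentile 16.75) within them.

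**Figure D3:**
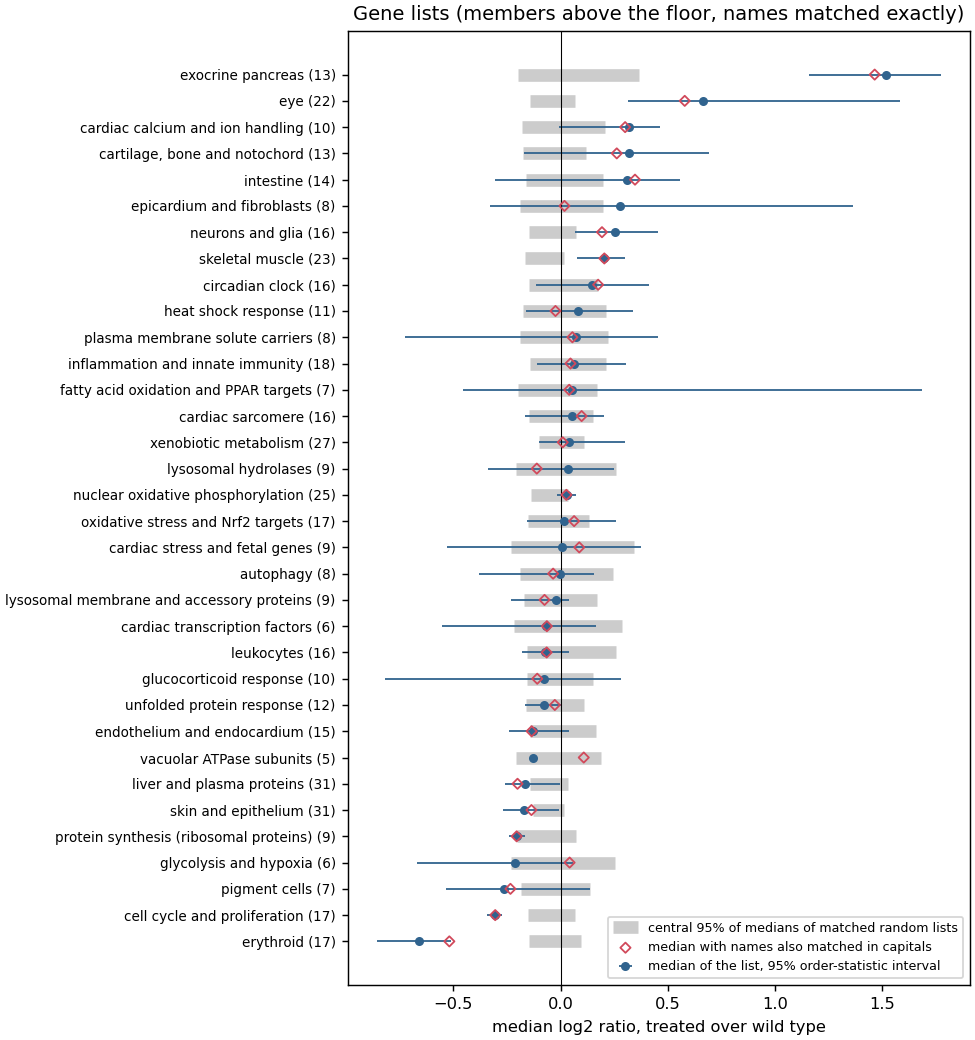
Median log2 ratio of treated over wild type for each reported list with a percentile (filled points, names matched exactly, number of members above the floor in brackets), with its exact 95% order-statistic interval where at least 6 members allow one, the central 95% of medians of matched random lists (grey bars) and the median under the wider matching (open diamonds). Exocrine pancreas (1.52) and eye (0.66) lie highest and erythroid (-0.66) lowest; the diamond lies on the other side of 0 for lysosomal hydrolases, vacuolar ATPase subunits, glycolysis and heat shock.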

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

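No paired analysis was possible because each group holds 1 library. The wider matching of list names was chosen after seeing the data, as was leaving out the eye and exocrine pancreas lists; the other settings were fixed before. The counts of higher and lower genes were 532 and 143. They became 598 and 123 with total counts, 533 and 143 with median-of-ratios factors, 521 and 150 with upper-quartile factors, 501 and 132 with a prior of 2 counts, 547 and 147 without an interval, and 493 and 143 without eye and pancreas genes. Without a floor they were 685 and 235, with a floor of 5 CPM 181 and 33, with FPKM 334 and 81 (278 and 44 shared), at 1.5-fold 1204 and 523, at 4-fold 75 and 21, with intervals that exclude the fold of 2 161 and 33, and for genes with a symbol 401 and 74. Higher genes made up at least 69.7% of counted genes in each of these settings; none of them tests the direction of the ratio, and with exchanged labels the same shares would be of lower genes. A stricter fold, a higher floor or a need for a symbol can only take genes out of the counts. Of the 532 higher and 143 lower genes, 101 and 24 had at least 10 CPM in the higher library. Most counted genes thus stood at low levels, where a higher floor removes them. For FPKM the cause was not tested.

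Of the 35 lists with a percentile, none differed in call under the other scalings, the prior of 2 counts or 40 bins. A floor of 5 CPM turned intestine to -0.028, took epicardium and fibroblasts (0.105) into the random range and endothelium (-0.156) below it. FPKM put nuclear oxidative phosphorylation above it (0.099), leaving out the most abundant member did so for the circadian clock (0.226), and no floor put ribosomal proteins (-0.203) below it. The wider matching took these lists out of the random range: hydrolases -0.111, vacuolar ATPase 0.108, cardiac sarcomere 0.098, endothelium -0.135, nuclear oxidative phosphorylation 0.027, fatty acid oxidation 0.040, glycolysis 0.042, oxidative stress 0.063, circadian clock 0.175 and ribosomal proteins -0.205. It took epicardium and fibroblasts into that range (0.018), and 24 lists had the same call under both matchings. Which members entered differs by construction; the cause beyond that was not tested. Lists with under 5 members left have no value: cardiac transcription factors and cardiac stress genes at 5 CPM, and vacuolar ATPase without its most abundant member. Of 148 named genes, none whose counting interval excluded a ratio of 1 turned its direction, but with total counts 11 intervals came to include 1 and 11 to exclude it, and with upper-quartile factors 3 and 1. Depth limits genes near 1 CPM.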

Other observations

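The early heterochronic and pituitary tests below were written before their results were seen, and the other tests after. The following lists were written after the data were examined and use the wider matching of names. Rod and cone photoreceptor genes had a median log2 ratio of 2.16 (1.58 to 2.37), with 22 of 25 members at least 2-fold higher in the treated library, while retinal field and pigment epithelium genes had 0.40 (0.04 to 0.49, 21 members). Genes of neural progenitors and neurogenesis, such as her4.3, had -0.55 (-0.67 to -0.35), with 30 of 34 intervals below a ratio of 1. Of the hatching gland genes, 4 were above the floor and 3 were at least 2-fold lower, with a median of -2.05. Skeletal-muscle contractile genes took 4.95% of the counts in wild type and 5.76% in the treated library, with a median of 0.24 (0.05 to 0.32, 13 members). The list of heart-specific contractile and natriuretic peptide genes took 0.008% and 0.007%, with a median of -0.31 (-0.54 to 0.10, 9 members, percentile 0.37). It lay below the random lists, but it was written when ratios of heart genes could be seen, so its place is not independent evidence. The interval of its median includes 0, and 4 of 9 members had an interval below a ratio of 1. The cardiac sarcomere list of the wider matching (0.098, percentile 99.7), which also holds genes of other muscle, lay above the random lists.

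The ratio of photoreceptor genes was weighed against 3 explanations. More eye tissue in the treated library would raise lens genes alike, but their median was 0.352 (0.31 to 0.40, 25 members), below the photoreceptor interval, so a larger eye share alone does not account for the pattern and leaves room for a smaller part. The libraries' depth ratio of 0.988 argues against depth. A later developmental stage of the treated library is a hypothesis consistent with lower early heterochronic genes (median -0.191, -0.43 to -0.06, 14 members), while pituitary hormone genes (0.141) had 3 members above the floor, too few to decide. An effect of salvianolate on development and a difference in age at collection cannot be told apart with 1 library per group, and neither can be told from an exchange of library labels.

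Lower lysosomal hydrolase genes appeared only with the wider matching, and these tests use it; 18 of 56 members had an interval below a ratio of 1 and 2 above. A possible explanation was that hatching gland genes and other strongly lower members alone made the pattern. Without ctslb and ACP5, the 2 members that were at least 2-fold lower, the percentile of the median was 0.46. Leaving out 2 of 56 members hardly moves a median, so this decides nothing about a few strong members. A lower abundance of the whole lysosome, by the amount of the hydrolases, was tested with the vacuolar ATPase genes. Their median was 0.108 (percentile 99.9, 12 of 24 intervals above a ratio of 1). Its lower bound of -0.07 lies above the hydrolase median of -0.111, which by the test's rule counts against the explanation. That rule was exchanged for one that asks for intervals that do not overlap, and was then set back. Both steps came after the result was seen. The hydrolase interval (-0.24 to -0.02) overlaps the vacuolar ATPase interval (-0.07 to 0.22). Under exact names the order was reversed, with -0.13 for vacuolar ATPase and 0.03 for hydrolases. The test therefore leaves the explanation open. The membrane list (-0.075, -0.147 to 0.017) lay within the random lists. Its interval includes both the hydrolase median and 0, so it does not count against the explanation. Fewer leukocytes cannot be told apart from lower expression per cell, since the interval of the leukocyte median (-0.065, -0.17 to 0.00) includes the hydrolase median, and an effect of the treatment was not tested apart from it.

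Both libraries are labelled as cardiac tissue, but 39.4% of genes above the floor in the wild-type library and 46.7% in the treated library were more abundant than MYL7. A library made mostly of heart muscle would hold MYL7 among its most abundant transcripts, so this argues against that source. Libraries from whole embryos or larvae remain a candidate explanation, in line with the abundance of skeletal muscle, lens and keratin genes; no sample of known origin was used here to test it.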
